A study of Mus musculus with 7 samples.

How the data were processed

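RNA from adult mouse hepatocytes, from fibroblasts of mouse embryos (MEF) and from induced hepatocyte-like cells (iHep) was labelled with Cy3 and hybridised to Agilent 1-colour whole-genome arrays, with 1 array per sample. Per the labels, the cells came from C57BL/6 mice, the 3 MEF samples were prepared individually from embryos, and the iHep arrays hold 3 types of iHep cells, numbered 1 to 3. The 7 arrays were 3 MEF arrays, 3 iHep arrays with 1 per type, and 1 hepatocyte array. Each array was taken to its group by its label alone.

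Per the file headers, the scanner images were read with Agilent Feature Extraction 9.5.1.1, which subtracts background from each spot, removes spatial trends and replaces signals at background by small positive surrogates. The processed signal of each spot is an intensity on a linear scale that was deposited without scaling between arrays. The mean and local background signals of each spot, also intensity values per the file headers, were used only for 1 alternative. The deposited files also hold 0 or 1 flags per spot, a unit other than a measurement, which mark spots as well above background, saturated, or outliers. The authors also deposited a table of processed values, 1 intensity per probe and array on a linear scale. Its 7 columns share 1 distribution, with medians from 66.3 to 66.4, and each correlated with the log2 scanner signal of its own array at r = 0.9988 to 0.9999 across probes. Its direction is thus settled, but how its values were made is not given in the sources used here, so it served as an alternative only.

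Of the 43379 spots that were not controls, spots with a non-uniformity or population outlier mark (66 to 104 per array) were left out, and repeated spots of a probe were averaged. That left 41138 of 41174 probes, since 36 had no usable spot on at least 1 array. The level of a probe is log2 of its processed signal minus the 75th percentile of log2 signal on its array, so a level of 0 is the 75th percentile. Probes took gene names from the GRCm38.p6 table by accession (24358 probes) or by symbol or synonym (8714 probes). Another 7805 kept the name in the scanner file and 261 had none. Where a gene had several probes, the brightest over all arrays stood for it, and disagreement between probes is stated where such a gene is described. Of 27583 genes and unnamed probes, 19135 were tested because the probe was well above background on every array of at least 1 group. Positions are those of the array's own annotation in the scanner files, genome build mm8. Exon and intron annotation of that build was not used here.

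The MEF 2 and MEF 3 arrays differed by no more than repeated spots of 1 probe on a single array do, except slightly among the dimmest spots. The array carries 245 probes with 10 spots each. In classes of signal below 100, from 100 to 1000, from 1000 to 10000 and above 10000, the robust SD of the log2 difference between these arrays was 1.03, 0.89, 0.66 and 0.53 times the SD that repeated spots predict. For MEF 1 against MEF 2 these ratios ran from 2.46 to 4.05. Although the series describes the 3 MEF samples as individually prepared, MEF 2 and MEF 3 were therefore averaged and counted as 1 sample, giving MEF n = 2, iHep n = 3 and hepatocyte n = 1. The decision departs from the design with 3 separate MEF samples that had been fixed before the data were examined, and it was made after the counts under that design had been seen. It rests on the noise between arrays, and counts under the earlier design are printed beside the main ones.

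Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 3 groups in 1 fit), with Benjamini-Hochberg adjustment over the 19135 genes and calls at an adjusted p under 0.05. All adjusted p-values of genes are from this test, and errors of log2 changes are standard errors. The spread came from the MEF and iHep samples, so the lone hepatocyte array was assumed to vary like the other groups. A second fit took each iHep type as its own group, which leaves the difference between the 2 MEF samples as the only measure of spread. Differences among the types were not tested because each has 1 array. Precision is limited by the number of arrays. The p-values measure only the spread between these samples, which for the iHep group is the spread between types.

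A fold is given as "at least N-fold" where the probe was not well above background on any array of the dimmer group, or was saturated on every array of the brighter one. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest level well above background on that array and the probe's own level. Fitted log2 changes of such genes are no bounds.

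A total of 32 gene lists were written before the data were examined. They cover hepatocyte functions, fibroblast and mesenchymal genes, epithelial genes, markers of other liver, gut, blood, nerve and muscle cells, and general processes. Each was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. Of the 1335 entries, 27 were not on the array. List p-values below are from camera. Counts of called members are given over all genes and, in these words, adjusted over the list alone.

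Genes to be named were set by a rule, also fixed before the data were examined. For each comparison it takes the 8 highest and 8 lowest genes by log2 change, among called genes with a standard symbol, a change of at least 1 and no overlap between the arrays of both groups. It adds up to 4 called members of the largest change per list, up to 3 members of the largest change that were not called, a set of liver, epithelial, fibroblast and growth genes named whatever their result, and the 5 genes per iHep type furthest from the mean of the other types. Genes named outside this rule are said to be so. Some genes that the rule takes are not reported here.

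Overlap between comparisons with shared MEF samples was set against 50 simulations with unchanged iHep and hepatocyte groups and against the overlap of independent lists. The fit was tested on simulated data with 200 genes changed in each of 5 runs over 19135 genes. Between iHep and MEF it recovered 2% of genes changed 2-fold, 58.5% at 4-fold, 84% at 8-fold and 97.5% at 32-fold, and called 7.4 unchanged genes per run. Between hepatocyte and MEF it recovered 0%, 15%, 66.5% and 94% at these folds, and between iHep and hepatocyte 0%, 23.5%, 69% and 93.5%. For a single iHep type against MEF it recovered 0%, 0.5%, 5% and 68%. A simulated list raised 4-fold between iHep and MEF was called by camera in 5 of 5 runs, and 0 of 150 unchanged lists were, over the same 19135 genes. Simulated genes varied independently of one another, so this does not test how often the preset correlation calls unchanged lists of correlated genes. The correlation estimated from the data ran from -0.023 (glucose and glycogen metabolism) to 0.608 (proliferation) over the lists.

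Slides and scans were tested as batches. Slide 1 held MEF 1 and all 3 iHep arrays, slide 2 held MEF 2 and MEF 3, and slide 3 held the hepatocyte array. The arrays of slide 2 were scanned on another day. Hepatocyte and slide 3 cannot be told apart. The slide was fitted as a block, which for iHep against MEF is the comparison within slide 1. Other alternatives were normexp background correction, quantile scaling, median centring, the deposited value table, other filters on dim probes, the mean of a gene's probes, limma with trend and robust options, stricter thresholds, a fit of MEF and iHep alone, and leaving out each replicate. The fits with MEF 2 and MEF 3 as separate samples, with and without a replicate block, and with 1 MEF sample for each comparison were added after the data had been seen. The last takes MEF 1 for 1 comparison and the mean of MEF 2 and MEF 3 for the other, with spread from the iHep samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.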

Results

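Gene expression was measured on 7 arrays of 3 groups, which were fibroblasts prepared from mouse embryos (MEF, 3 arrays), induced hepatocyte-like cells (iHep, 3 types with 1 array each) and hepatocytes from adult liver (1 array). iHep cells are fibroblasts turned towards a hepatocyte state by added transcription factors, and the study is known to have used Hnf4a with Foxa1, Foxa2 or Foxa3. The labels call the types 4α1, 4α2 and 4α3, here types 1, 2 and 3. What the last digit stands for is not given in the sources used here. The 75th percentile of signal ran from 624 on the hepatocyte array to 1583 on MEF 2, and 60.2% to 68.7% of probes were well above background. MEF 2 and MEF 3 differed by no more than repeated spots on 1 array do, apart from a slight excess among the dimmest spots, and were counted as 1 sample. This departs from the planned design of 3 MEF samples. They had 74 of 17270 genes over 2-fold apart against 1190 of 16139 between MEF 1 and MEF 2. Levels below are log2 signal relative to the array's 75th percentile. Changes are given ± SE from limma over MEF n = 2, iHep n = 3 and hepatocyte n = 1, and adjusted p-values are Benjamini-Hochberg values over 19135 genes.

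The first comparison, iHep against MEF, asks what differs between the induced cells and the cell type they came from. Genes of liver plasma proteins, of gut and stomach mucosa and of epithelial structure had the highest fitted changes. Ahsg, which encodes the plasma protein fetuin-A, rose by 15.83 ± 0.81 on the log2 scale (at least 13220-fold, adjusted p = 0.000818), Fgb, the fibrinogen beta chain, by 15.12 ± 0.39 (at least 14250-fold, adjusted p = 0.000325) and Apoa1, the main protein of high-density lipoprotein, by 14.68 ± 0.65 (at least 8243-fold, adjusted p = 0.000582). The mucosal genes Tff3, a trefoil peptide of mucus-secreting gut cells, and Gkn2, a gastrokine of the stomach lining, rose by 15.96 ± 0.66 (at least 18020-fold, adjusted p = 0.000582) and 14.88 ± 0.46 (at least 7378-fold, adjusted p = 0.000386). Cdh1, the epithelial adhesion protein E-cadherin, rose by 12.85 ± 0.28 (at least 2140-fold, adjusted p = 0.000308). Vil1, an actin-bundling protein of microvilli, and Clca1, a goblet cell product, rose by 13.28 ± 0.74 (at least 2427-fold) and 12.77 ± 0.56 (at least 5538-fold). None of these 8 genes was well above background on any MEF array, so their folds are bounds and their order among all genes is not established. Each was above every MEF array on all 3 iHep arrays, which the rule for naming the highest genes required.

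The largest decreases included 2 genes of the extracellular matrix. Mfap4, a protein of elastic microfibrils, fell by 11.05 ± 0.50 on the log2 scale (2115-fold, adjusted p = 0.000605) and Aspn, a small proteoglycan, fell by 9.18 ± 0.90 (581-fold, adjusted p = 0.00386). C1qtnf3, Vat1l, Fxyd6, Jph2, Piezo2 and Cxcl14 fell by between 9.40 and 8.98. Each was lower on all 3 iHep arrays than on every MEF array, as the rule for naming the lowest genes required. Mfap4, Aspn and Cxcl14 were well above background on 2 of the 3 iHep arrays. Fxyd6 fell 544.5-fold and Cxcl14 504.5-fold, while C1qtnf3, Vat1l, Jph2 and Piezo2 were not well above background on any iHep array and were lower at least 201-fold, 121.5-fold, 149.3-fold and 105-fold. The probe of Mfap4 lies on chromosome 11 at 61304789 to 61304848 of build mm8. Those of Ahsg, Tff3, Gkn2 and Cdh1 lie on chromosome 16 at 22814676 to 22814735, chromosome 17 at 30852346 to 30852405, chromosome 6 at 87344925 to 87344984 and chromosome 8 at 109559041 to 109559100.

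**Figure D1:**
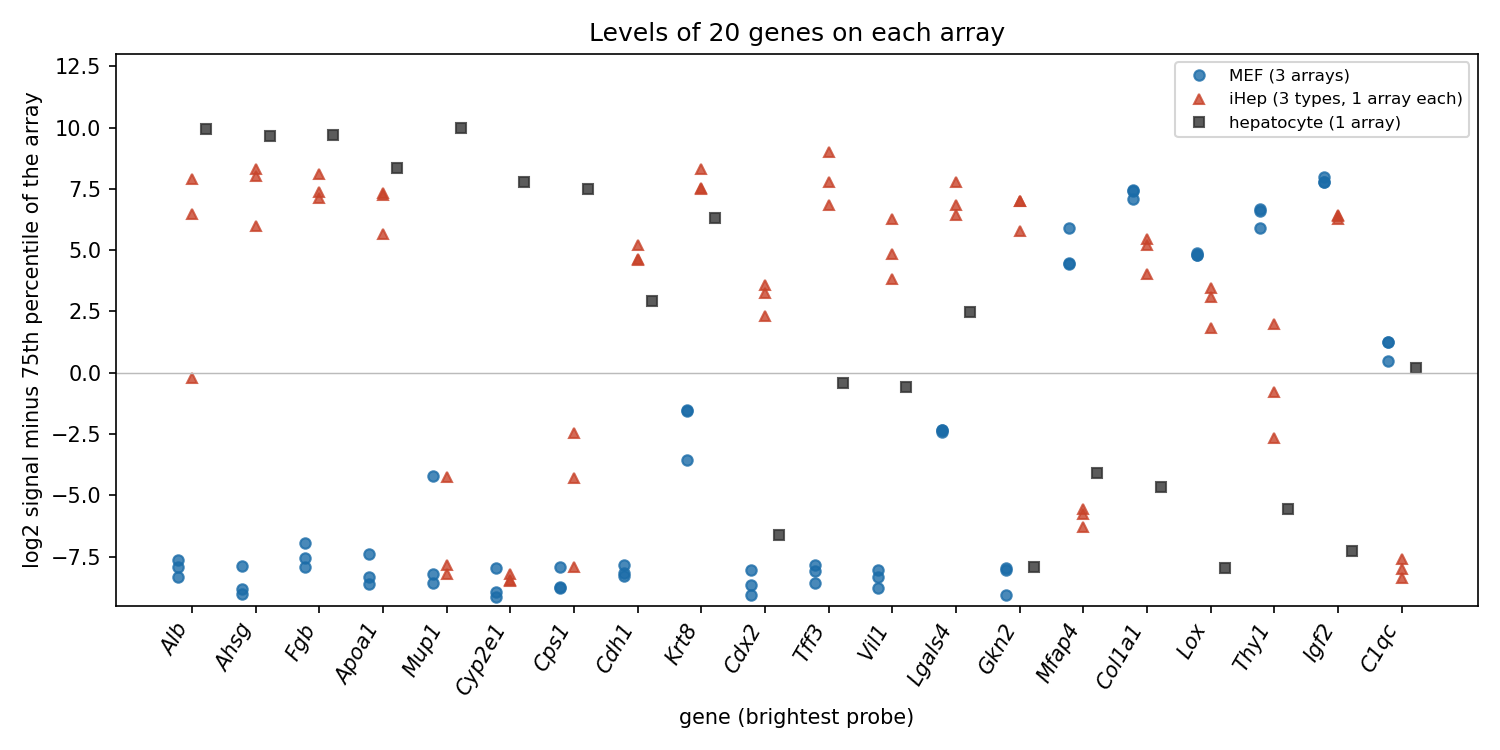
Levels of 20 genes on each of the 7 arrays, as log2 signal minus the array's 75th percentile, with circles for MEF, triangles for iHep and a square for the hepatocyte array. Cdh1 lay from 4.59 to 5.20 on the iHep arrays and at 2.91 on the hepatocyte array, while Alb spanned -0.21 to 7.92 over the iHep types, and Mup1 was far higher on the hepatocyte array than on any other.

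Liver genes named whatever their result differed in how evenly they moved. Alb, serum albumin, rose by 12.67 ± 2.50 (at least 2019-fold, adjusted p = 0.0245), with levels of 6.46, 7.92 and -0.21 in types 1, 2 and 3 against 9.95, at saturation, in hepatocytes. Ttr, a thyroid hormone carrier, rose by 6.03 ± 1.02 (at least 17.8-fold, adjusted p = 0.0162) and Afp, the fetal counterpart of albumin, by 7.71 ± 1.63 (adjusted p = 0.0295). Hnf4a, a nuclear receptor that directs hepatocyte genes, rose by 7.80 ± 1.24 (at least 53.23-fold, adjusted p = 0.0139) at its brightest probe, and 1 of its other probes was detected on 2 MEF arrays. Foxa1 (0.81 ± 1.71, adjusted p = 0.766), Foxa2 (-0.57 ± 2.46, adjusted p = 0.887) and Foxa3 (0.59 ± 0.28, adjusted p = 0.201) did not pass the test. Foxa1 and Foxa2 were well above background in type 1 alone among the iHep arrays, and Foxa3 in none. Whether these probes read the introduced transcripts as well as the cells' own is not given in the sources used here, so the values of Hnf4a and Foxa1 to Foxa3 do not separate them. Cps1, the first enzyme of the urea cycle, was detected in types 2 and 3 only (3.46 ± 1.63, at least 2.581-fold, adjusted p = 0.190), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was not well above background on any MEF or iHep array.

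Lists of hepatocyte functions moved up in part. Of 49 tested liver secreted proteins, 21 rose and 1 fell (22 and 3 adjusted over the list alone), with a median log2 change of 2.14, or 1.89 with members at their bounds, and 2.19 within slide 1 (adjusted p = 1.42e-07, and adjusted p = 0.302 with an estimated correlation). Serpina1d, an antitrypsin, rose by 11.08 ± 1.17, whereas Vtn (2.53 ± 1.66) and Igf1 (-3.81 ± 1.21) were not called. Among 55 cytochrome P450 and phase I enzymes 21 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 2.35, 2.22 with bounds and 2.19 within slide 1 (adjusted p = 2.15e-08, and adjusted p = 0.235 with an estimated correlation). Against MEF 1 on the same slide the median was 1.32, 3.95 and 1.22 in types 1, 2 and 3, so type 2 weighs most. Cyp3a13 rose by 9.54 ± 0.62 (at least 261.5-fold) and Cyp4f14 by 9.34 ± 0.47 (at least 152.6-fold), while Cyp2a5 (6.18 ± 2.81, at least 16.83-fold) was not called. Phase II conjugation enzymes had 12 of 40 members higher and 0 lower (12 and 1 adjusted over the list alone), led by the glutathione transferases Gsta2 (12.19 ± 0.59, 4675-fold) and Gsta1 (11.74 ± 0.34, 3419-fold). Their median was 0.55, 0.39 with bounds and 0.24 within slide 1 (adjusted p = 0.000124, and adjusted p = 0.231 with an estimated correlation). In coagulation and complement 9 of 34 rose and 0 fell (9 and 0 adjusted over the list alone), among them the complement genes Cfb (10.76 ± 0.41, 1733-fold) and C3 (8.69 ± 0.71). The median was 0.56 and 0.45 within slide 1 (adjusted p = 0.00164, and adjusted p = 0.277 with an estimated correlation). By type, against MEF 1 on the same slide, it was 0.24, 1.12 and 0.38 in types 1, 2 and 3, so type 2 weighs most here too. Of 36 genes of bile acid synthesis and hepatic transport 10 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.22 and 0.21 within slide 1 (adjusted p = 0.00981, and adjusted p = 0.271 with an estimated correlation). Acox2, Slc27a2 and Cyp27a1 were among them.

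Hepatocyte transcription factors had 11 of 38 members higher and 2 lower (14 and 3 adjusted over the list alone), including the xenobiotic receptor Nr1i2 (7.37 ± 0.84). The median was 0.71 and 0.74 within slide 1 (adjusted p = 0.00331, and adjusted p = 0.231 with an estimated correlation). Of 46 genes of fatty acid oxidation 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.44 and 0.52 within slide 1 (adjusted p = 0.00127, and adjusted p = 0.302 with an estimated correlation). They included Pdk4 (5.04 ± 0.54), a kinase that holds back pyruvate oxidation, and Acsl1 (4.54 ± 0.40), which activates fatty acids. Pdk4 also led the list of glucose and glycogen metabolism, where 9 of 34 rose and 2 fell (12 and 3 adjusted over the list alone), with a median of 0.80 and 0.74 within slide 1 (adjusted p = 0.000178, and adjusted p = 0.231 with an estimated correlation). In the urea cycle and amino acid list only 6 of 53 rose and 3 fell (6 and 3 adjusted over the list alone), with Glul, glutamine synthetase, up by 4.82 ± 0.20 and Ass1, an enzyme of the urea cycle, down at -4.23 ± 0.39. This list's median was 0.31 (adjusted p = 0.0488, and adjusted p = 0.234 with an estimated correlation) and 0.51 within slide 1, where it was not called (adjusted p = 0.226). By type, against MEF 1 on the same slide, its median was only 0.01, 0.36 and -0.17 in types 1, 2 and 3. Acute phase and inflammation genes had 18 of 35 higher and 1 lower (22 and 3 adjusted over the list alone), among them Lcn2 (12.06 ± 0.67, at least 1001-fold), Saa3 (9.19 ± 1.31) and Saa2 (8.69 ± 0.52, at least 161.6-fold). The median was 2.30 and 2.32 within slide 1 (adjusted p = 1.29e-07, and adjusted p = 0.231 with an estimated correlation). Fetal liver genes went both ways, with 4 of 25 higher and 5 lower (5 and 6 adjusted over the list alone), and the list was not called (median -0.53, mean 0.64, -0.54 within slide 1, camera direction down, adjusted p = 0.519). Mest fell by 4.36 ± 0.76 there.

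Epithelial genes rose as a group. Of 55 tested genes of epithelial junctions and keratins 44 rose and 0 fell (45 and 0 adjusted over the list alone), with a median of 5.14, or 4.77 with members at their bounds, and 5.35 within slide 1 (adjusted p = 3.64e-22, and adjusted p = 0.231 with an estimated correlation). The tight junction gene Cldn2 rose by 10.73 ± 0.28 (at least 470.5-fold) and the keratin gene Krt8 by 10.31 ± 0.66 (1272-fold). Krt19, a keratin gene held in the list of bile duct markers instead, rose by 5.73 ± 0.25 (53.03-fold). The list of intestinal epithelium had 23 of 53 members higher and 3 lower (23 and 4 adjusted over the list alone), with a median of 2.07, 1.82 with bounds and 1.43 within slide 1 (adjusted p = 2.51e-07, and adjusted p = 0.231 with an estimated correlation). Cdx2, the homeobox factor of intestinal identity, rose by 11.51 ± 0.48 (at least 631.3-fold, adjusted p = 0.000582), with a probe on chromosome 5 at 147611320 to 147611379. Tff1, a trefoil peptide of the stomach, rose by 11.83 ± 1.02 (3639-fold), and Spink4 and Olfm4 were not called. Among 27 stomach and pancreas genes 7 rose and 6 fell (8 and 6 adjusted over the list alone), with Amy2 up by 9.18 ± 0.77 (at least 271.8-fold) and the pancreatic factor Pdx1 by 5.96 ± 0.67 (at least 22.77-fold). That list was not called, and its median (-0.09, and -0.18 within slide 1) was negative while its mean (1.08) and camera direction were positive (adjusted p = 0.770). Bile duct markers had 12 of 33 higher and 6 lower (13 and 6 adjusted over the list alone), among them Tspan8 (10.75 ± 0.40), Elf3 (9.43 ± 0.79, at least 143.9-fold) and Epcam (8.64 ± 0.68, at least 173.5-fold). The median was 0.46 and 0.57 within slide 1 (adjusted p = 0.0106, and adjusted p = 0.234 with an estimated correlation). Sox9, a factor of ducts and progenitors, rose too (adjusted p = 0.00894), from -0.03 in MEF to 1.47 in iHep on average at its brightest probe.

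Fibroblast genes fell as a group but stayed detectable in many cases. Of 58 fibroblast and extracellular matrix genes 0 rose and 38 fell (0 and 46 adjusted over the list alone), with a median of -2.63 and -2.64 within slide 1 (adjusted p = 2.62e-12, and adjusted p = 0.302 with an estimated correlation). Col8a1 fell by 8.65 ± 0.93 and Lum fell by 8.43 ± 0.62, whereas Tnc (-3.27 ± 0.96) was not called. Col1a1, the main chain of type I collagen, fell by 2.37 ± 0.48 (5.173-fold, adjusted p = 0.0266) at its brightest probe, where its iHep level was still 4.89 ± 0.77 (SD, n = 3), and fell further at its other 2 probes. Among 65 mesenchymal regulators and surface markers 3 rose and 31 fell (5 and 35 adjusted over the list alone), with a median of -1.59 and -1.84 within slide 1 (adjusted p = 9e-07, and adjusted p = 0.235 with an estimated correlation). Thy1, a fibroblast surface protein, fell by 6.76 ± 1.37 (108.4-fold, adjusted p = 0.0265), and Foxc2 and Fgf10 fell by 6.51 ± 0.36 (at least 61.64-fold) and 6.05 ± 0.60 (at least 36.28-fold). Twist1, a mesenchymal transcription factor, was not called (-1.37 ± 0.39, adjusted p = 0.0657). Hox genes had 0 of 32 higher and 4 lower (0 and 1 adjusted over the list alone), led by Hoxd13 (-7.97 ± 2.01). The median was -0.90 and -0.50 within slide 1 (adjusted p = 0.00639, and adjusted p = 0.310 with an estimated correlation).

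Macrophage, endothelial and neural markers were also lower as lists in iHep than in MEF, in the same direction as the fibroblast genes. Of 27 Kupffer cell and macrophage genes 1 rose and 15 fell (1 and 19 adjusted over the list alone), with a median of -3.93, -3.59 with bounds and -3.73 within slide 1 (adjusted p = 9.72e-09, and adjusted p = 0.231 with an estimated correlation). The complement gene C1qc and the macrophage receptor Adgre1 were at 0.87 and 0.01 in MEF, on average, and not above background on any iHep array (at least 121.6-fold and 66.84-fold lower). Endothelial genes had 2 of 32 higher and 9 lower (2 and 10 adjusted over the list alone), including the growth factor receptor Kdr (-7.51 ± 0.33, at least 67.49-fold) and Erg (-7.89 ± 0.85, at least 59.93-fold). The median was -0.91, -0.68 with bounds and -0.68 within slide 1 (adjusted p = 0.0104, and adjusted p = 0.231 with an estimated correlation). Neural genes had 1 of 21 higher and 8 lower (1 and 9 adjusted over the list alone), with Stmn2 down at -5.45 ± 0.31 (at least 9.532-fold) and a median of -0.68, and -0.38 within slide 1 (adjusted p = 0.0211, and adjusted p = 0.325 with an estimated correlation). The remaining marker lists were not called. Muscle genes had 2 of 24 higher and 6 lower (2 and 7 adjusted over the list alone, median -0.50, -0.93 within slide 1, adjusted p = 0.0904), with Des at -5.30 ± 0.57 and Myh7 at 5.27 ± 0.93. Stellate cell genes had 2 of 20 higher and 8 lower (2 and 10 adjusted over the list alone, median -1.34, -1.08 with bounds, adjusted p = 0.0769), and this list was called within slide 1 (median -1.67, adjusted p = 0.0404). Blood and lymphocyte genes had 3 of 22 higher and 2 lower (3 and 2 adjusted over the list alone, adjusted p = 0.825), with a median of -0.13, and -0.09 within slide 1, against a mean of 0.42 and an upward camera direction. Ptprc, a marker of blood cells, fell by 5.34 ± 0.43 (at least 9.54-fold). Pluripotency genes had 1 of 13 higher and 2 lower (1 and 2 adjusted over the list alone, median -0.64, -0.54 within slide 1, adjusted p = 0.198), with Sox2 at -3.17 ± 0.46 (at least 2.582-fold) and Klf4 at 1.56 ± 0.32.

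Among general processes, interferon response genes were higher as a list, with 15 of 44 higher and 0 lower (23 and 0 adjusted over the list alone) and a median of 2.06, and 1.39 within slide 1 (adjusted p = 1.49e-10, and adjusted p = 0.302 with an estimated correlation). The antiviral genes Oas2, Mx1 and Oas3 rose by 9.09 ± 0.40 (546.1-fold), 6.91 ± 0.55 (at least 43.94-fold) and 4.65 ± 0.26. Genes of cholesterol and fatty acid synthesis fell, with 1 of 44 higher and 24 lower (4 and 31 adjusted over the list alone) and a median of -1.45, and -1.41 within slide 1 (adjusted p = 2.98e-07, and adjusted p = 0.234 with an estimated correlation). The sterol synthesis enzymes Mvd and Cyp51 fell by 2.70 ± 0.23 and 2.65 ± 0.22, whereas Dgat2, an enzyme of triglyceride synthesis, rose by 3.45 ± 0.53. Hepatocytes differed from MEF the other way, with 25 of these 44 genes higher and 4 lower (25 and 4 adjusted over the list alone, median 1.32, adjusted p = 0.000535, and adjusted p = 0.285 with an estimated correlation). Imprinted genes had 1 of 24 higher and 12 lower (2 and 16 adjusted over the list alone), with a median of -1.54, -1.39 with bounds and -1.32 within slide 1 (adjusted p = 0.00183, and adjusted p = 0.302 with an estimated correlation). Grb10 fell by 6.01 ± 1.03 and Igf2, a fetal growth factor, fell by 1.52 ± 0.18 (adjusted p = 0.0063), while H19 was not called (-0.25 ± 0.42, adjusted p = 0.697). Immediate early genes had 5 of 30 higher and 1 lower (5 and 1 adjusted over the list alone), with Myc up by 2.82 ± 0.24 and a median of 0.80, and 0.99 within slide 1 (adjusted p = 0.0215, and adjusted p = 0.571 with an estimated correlation). Against MEF 1 on the same slide this median was 0.36, 0.59 and 1.98 in types 1, 2 and 3, so type 3 weighs most. Proliferation genes did not differ as a group, with 2 of 67 higher and 0 lower (1 and 0 adjusted over the list alone) and a median of -0.15, and -0.20 within slide 1 (adjusted p = 0.991), and Mki67, a marker of dividing cells, was not called (0.15 ± 0.29, adjusted p = 0.752). The p53 list had 2 of 32 higher and 2 lower (0 and 0 adjusted over the list alone, median -0.11, -0.27 within slide 1, adjusted p = 0.568), and Cdkn2a, a cell cycle inhibitor, was not called (-1.58 ± 0.83, adjusted p = 0.227). Housekeeping genes had 2 of 26 higher and 1 lower (0 and 0 adjusted over the list alone, median -0.02 with an upward camera direction, 0.01 within slide 1, adjusted p = 0.863).

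Over all genes, limma called 4459 of 19135 (23.3%), of which 1924 were higher and 2535 lower in iHep. In 307 of the higher and 522 of the lower genes the dimmer group was not well above background on any array, so that the fold is a bound. The design with MEF 2 and MEF 3 as separate samples called 7307, with 3158 higher and 4149 lower. Within slide 1, which is also the fit with slide as a block, 1669 genes were called, of which 1574 were among the 4459, and all 4459 kept their direction there. The count was 1905 without MEF 1 and 2890 without iHep type 1. The shared direction within slide 1 is no check on the slide, since 4455 of the 4459 genes had no overlap between single MEF and iHep arrays. Their direction against MEF 1 was thus set beforehand. Of the 32 lists, 23 were called, 15 up and 8 down, and 0 with an estimated correlation.

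**Figure D2:**
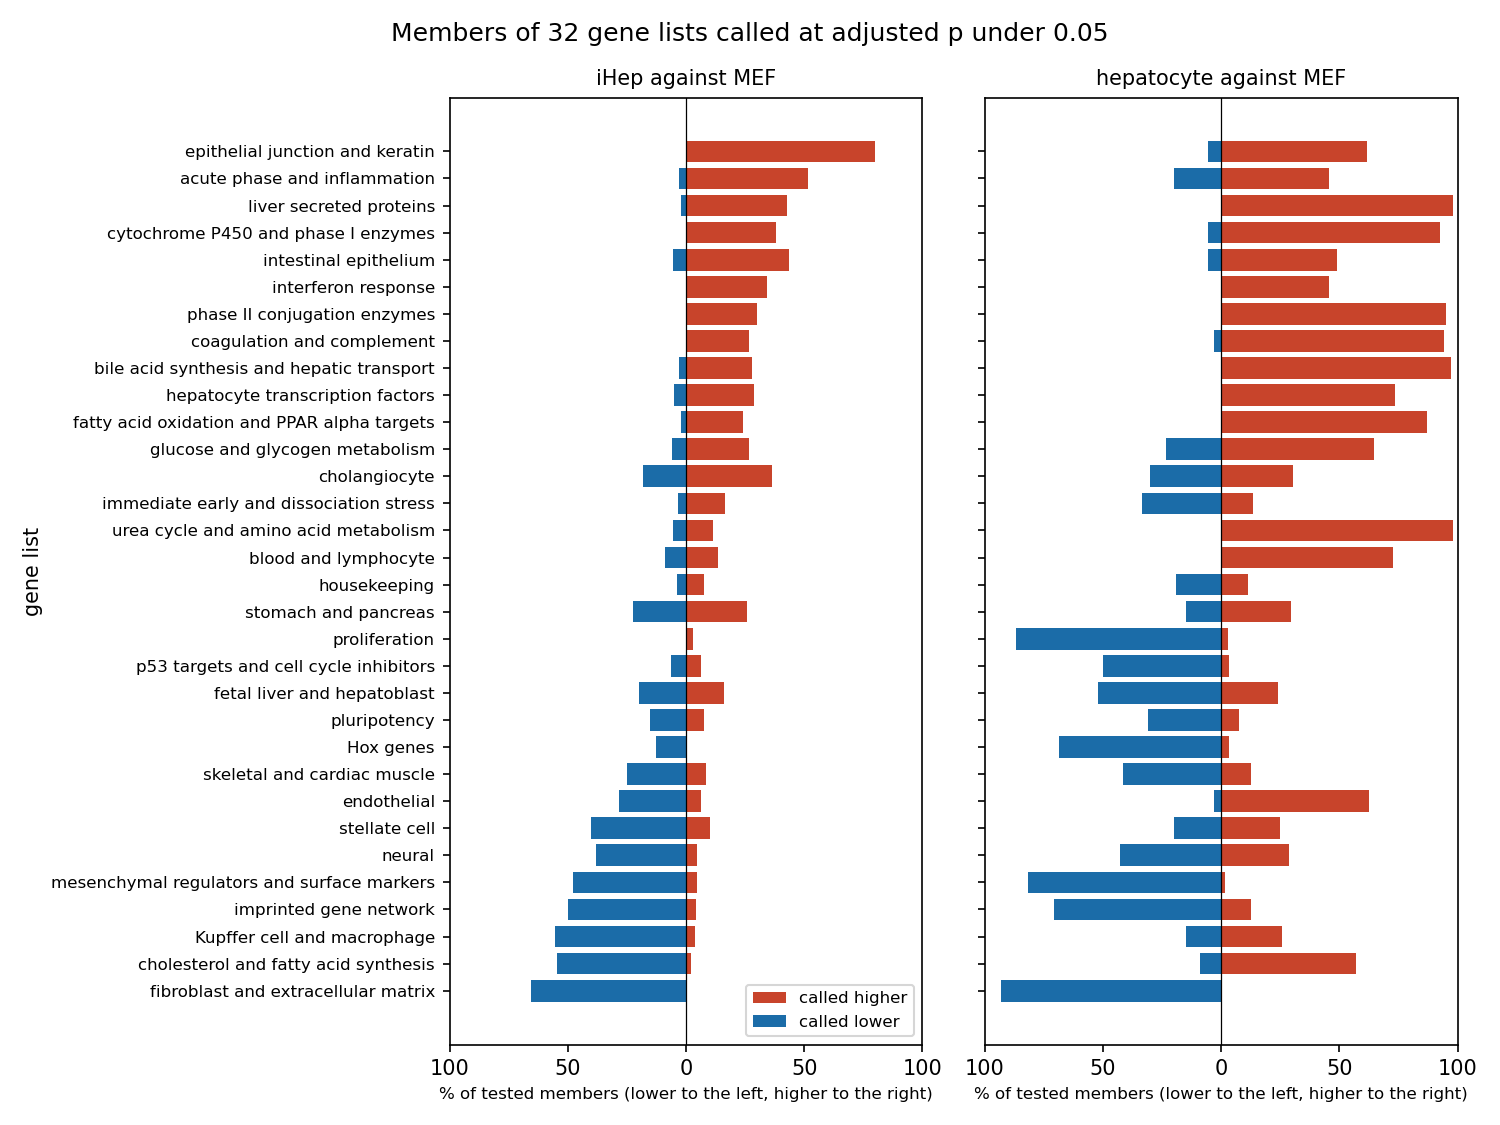
Share of tested members called higher (right) or lower (left) in each of 32 gene lists, in percent, for iHep against MEF and for hepatocyte against MEF. Among epithelial genes 44 of 55 were higher in iHep and 34 of 55 in hepatocytes, whereas urea cycle and amino acid genes were higher for 6 of 53 and 52 of 53.

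The second comparison, hepatocyte against MEF, gives the reference for a liver profile on the same array type. The 8 genes with the highest fitted changes were all of liver secretion or metabolism, with no MEF array well above background, so their order is not established. Ahsg rose by 18.03 ± 1.09 on the log2 scale (at least 61000-fold, adjusted p = 0.000402), Alb by 17.90 ± 3.36 (at least 75850-fold, adjusted p = 0.00976) and Fabp1, the liver fatty acid binding protein, by 17.75 ± 3.01 (at least 50200-fold, adjusted p = 0.00713). The others were the carboxylesterases Ces1c and Ces3b, prothrombin (F2, 17.52 ± 0.75, at least 51760-fold), Fgb and Serpina1b. Among the genes with the lowest fitted changes, Igf2 fell by 15.14 ± 0.24 (at least 12750-fold, adjusted p = 0.000168), and its probe lies on chromosome 7 at 142460185 to 142460245. Cnn1, Ptn, Il1rl1, Mgp, Lox, Prrx2 and Ogn were the others. None was well above background in hepatocytes, so their order is not established. Lox, which crosslinks collagen, fell by 12.78 ± 0.69 (at least 1534-fold).

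Most tested members of the hepatocyte lists were higher in hepatocytes. Liver secreted proteins had 48 of 49 higher and 0 lower (48 and 0 adjusted over the list alone), with a median of 12.84, or 11.93 with bounds (adjusted p = 3.76e-16, and adjusted p = 0.161 with an estimated correlation). Urea cycle and amino acid genes had 52 of 53 higher and 0 lower (52 and 0 adjusted over the list alone), with a median of 9.60, or 9.23 with bounds, and were the only list also called with an estimated correlation (adjusted p = 1.24e-18, and adjusted p = 0.0471 with an estimated correlation). Cps1 rose by 15.83 ± 2.19 (at least 13670-fold). Of 55 P450 and phase I enzymes 51 rose and 3 fell (51 and 3 adjusted over the list alone), with a median of 11.07, or 10.74 with bounds (adjusted p = 3.97e-13, and adjusted p = 0.161 with an estimated correlation), and Cyp2e1, which oxidises ethanol, rose by 16.31 ± 0.48 (at least 17090-fold). Coagulation and complement had 32 of 34 higher and 1 lower (32 and 1 adjusted over the list alone), with a median of 12.35, or 11.79 with bounds (adjusted p = 3.84e-13, and adjusted p = 0.111 with an estimated correlation). Phase II enzymes had 38 of 40 higher and 0 lower (39 and 0 adjusted over the list alone, adjusted p = 4.54e-14, and adjusted p = 0.0710 with an estimated correlation), and bile acid genes 35 of 36 and 0 (36 and 0 adjusted over the list alone, adjusted p = 3.64e-14, and adjusted p = 0.0710 with an estimated correlation). Hepatocyte transcription factors had 28 of 38 higher and 0 lower (31 and 0 adjusted over the list alone, adjusted p = 1.55e-08, and adjusted p = 0.0710 with an estimated correlation), including Hnf4a (12.88 ± 1.67, at least 1799-fold) and Foxa3 (10.15 ± 0.38, at least 295-fold), whereas Foxa1 (6.42 ± 2.29, at least 42.65-fold, adjusted p = 0.0660) and Foxa2 (9.04 ± 3.30, adjusted p = 0.0694) were not called.

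Fibroblast and dividing-cell genes were lower in hepatocytes. Fibroblast and matrix genes had 0 of 58 higher and 54 lower (0 and 55 adjusted over the list alone), with a median of -7.99, or -7.40 with bounds (adjusted p = 7.21e-17, and adjusted p = 0.237 with an estimated correlation), and Col1a1 fell by 11.90 ± 0.65 (3812-fold). Mesenchymal genes had 1 of 65 higher and 53 lower (1 and 55 adjusted over the list alone, adjusted p = 1.13e-14, and adjusted p = 0.120 with an estimated correlation). Proliferation genes had 2 of 67 higher and 58 lower (2 and 59 adjusted over the list alone), with a median of -4.02, or -3.83 with bounds (adjusted p = 3.76e-16, and adjusted p = 0.288 with an estimated correlation), and Mki67 fell by 4.37 ± 0.39 (20.66-fold). The endothelial, the blood and lymphocyte and the intestinal lists were higher on the hepatocyte array. Cell composition of this sample was not measured. Which of its cells held transcripts of endothelial, blood, Kupffer cell and stellate cell genes is therefore not known. Intestinal genes had 26 of 53 higher and 3 lower (27 and 3 adjusted over the list alone, median 2.94, 2.18 with bounds, adjusted p = 0.00015, and adjusted p = 0.161 with an estimated correlation). Blood and lymphocyte genes had 16 of 22 higher and 0 lower (16 and 0 adjusted over the list alone, median 2.34, 1.67 with bounds, adjusted p = 0.00015, and adjusted p = 0.120 with an estimated correlation). Endothelial genes had 20 of 32 higher and 1 lower (20 and 1 adjusted over the list alone, adjusted p = 3.57e-05, and adjusted p = 0.102 with an estimated correlation), the Kupffer cell genes Clec4f and Cd163 rose by 9.74 ± 0.50 (at least 211.1-fold) and 7.49 ± 0.44 (at least 42.29-fold), and the stellate cell gene Lrat rose by 6.00 ± 0.48 (at least 17.43-fold). Stellate cell genes as a list were not called, with 5 of 20 higher and 4 lower (5 and 4 adjusted over the list alone, adjusted p = 0.895), and a median of -0.17 and downward camera direction against a mean of 0.12. Bile duct genes were not called either, with 10 of 33 higher and 10 lower (11 and 10 adjusted over the list alone, median -0.17, adjusted p = 0.667). The Kupffer cell and macrophage list as a whole went both ways, with 7 of 27 higher and 4 lower (7 and 3 adjusted over the list alone, adjusted p = 0.992), and its median of -0.47 and camera direction were negative against a mean of 0.78.

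In all, limma called 10233 genes, 5430 higher and 4803 lower in hepatocytes, against 12021 with MEF 2 and MEF 3 separate. Of the 32 lists 23 were called. With 1 hepatocyte array on a slide of its own, cell type and slide cannot be told apart. Sex may differ as well. Xist, the transcript of the inactive X chromosome, was not well above background on the hepatocyte array (-7.89), against 1.26 to 1.87 on the MEF arrays. Ddx3y, a Y chromosome gene named outside the rule, lay at 2.64 on the hepatocyte array and was detected on the MEF arrays too. Quantile scaling moved the median change of all genes by -0.146 from 0.145 here, and by 0.198 from -0.174 in iHep against hepatocyte, where median centring moved it by 0.129, so small changes in these comparisons are relative to the scaling. With quantile scaling the balance of calls turned over, to 4945 higher and 5324 lower in hepatocytes than in MEF.

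The third comparison, iHep against hepatocyte, asks which liver genes the induced cells had not reached and which other genes they held. Gkn2 (14.50 ± 0.58, at least 5218-fold, adjusted p = 0.000192) and Igf2 (13.62 ± 0.23, at least 4444-fold, adjusted p = 0.000137) were among the genes with the highest fitted changes over hepatocytes, with Anxa8 (11740-fold), S100a6, Cxcl5, Scnn1g, Ffar4 and Cxcl17. The order of those with bounds is not established. The largest deficits included Mup1, a major urinary protein made by adult liver (-16.76 ± 2.21, adjusted p = 0.00373, well above background in type 2 alone among the iHep arrays), Mup5, the lectin Mbl2, Cyp2e1 (-16.18 ± 0.45, at least 14830-fold, adjusted p = 0.000137), Aadac and Agxt. Cyp2e1 and Agxt were not well above background on any iHep array. Alb was saturated in hepatocytes, so its difference is at least 37.56-fold, and with type 3 far below the other types it did not pass the test (-5.23 ± 3.16, adjusted p = 0.223). Nor did Krt8 (1.46 ± 0.83, adjusted p = 0.200), Gsta1 (0.38 ± 0.43, adjusted p = 0.486) or Glul (0.59 ± 0.25, adjusted p = 0.109).

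The lists differed in how far iHep stood from hepatocytes. Of the 52 urea cycle and amino acid genes higher in hepatocytes than in MEF, 6 were also higher in iHep than in MEF, and the list had 0 of 53 higher and 51 lower in iHep than in hepatocytes (0 and 51 adjusted over the list alone, median -8.78, adjusted p = 2.51e-18, and adjusted p = 0.0494 with an estimated correlation). The corresponding shares were 21 of 48 for liver secreted proteins, 18 of 51 for P450 and phase I enzymes, 9 of 32 for coagulation and complement and 10 of 28 for hepatocyte transcription factors. For cholesterol and fatty acid synthesis the share was 1 of 25. That list had 2 of 44 higher and 36 lower in iHep than in hepatocytes (2 and 40 adjusted over the list alone, median -2.59, adjusted p = 1.52e-09, and adjusted p = 0.163 with an estimated correlation). Liver secreted proteins had 0 of 49 higher and 39 lower (0 and 41 adjusted over the list alone, median -7.78, adjusted p = 4.4e-12, and adjusted p = 0.208 with an estimated correlation). P450 enzymes had 3 of 55 higher and 41 lower (3 and 45 adjusted over the list alone, median -8.16, adjusted p = 3.87e-09, and adjusted p = 0.178 with an estimated correlation). Hnf4a was lower at its brightest probe (-5.08 ± 1.57, adjusted p = 0.0474), while another of its probes read -0.52 in hepatocytes and -0.43, -0.24 and -2.09 in iHep types 1, 2 and 3. Some lists raised in iHep were not called lower there than in hepatocytes. Among them, the bile duct, immediate early and acute phase lists were not called higher in hepatocytes than in MEF either (camera adjusted p = 0.667, 0.107 and 0.0882). Of the 16 acute phase genes that were higher in hepatocytes than in MEF, 9 were lower in iHep than in hepatocytes. Of the 34 epithelial genes that were higher in hepatocytes than in MEF, 31 were also higher in iHep than in MEF. That list had 22 of 55 higher and 9 lower in iHep than in hepatocytes (22 and 9 adjusted over the list alone, median 1.09, adjusted p = 0.0286, and adjusted p = 0.533 with an estimated correlation). Bile duct genes had 16 of 33 higher and 7 lower (18 and 7 adjusted over the list alone, median 1.67, adjusted p = 0.0102, and adjusted p = 0.172 with an estimated correlation), with Krt19 up by 10.48 ± 0.32 (1429-fold). Immediate early genes had 12 of 30 higher and 2 lower (12 and 2 adjusted over the list alone, median 1.21, adjusted p = 0.0085, and adjusted p = 0.547 with an estimated correlation). Acute phase genes, with 17 of 35 higher and 9 lower (17 and 9 adjusted over the list alone, median 1.34, adjusted p = 0.167), and interferon response genes, with 6 of 44 higher and 5 lower (5 and 4 adjusted over the list alone, median -0.27 against a mean of 0.16 and an upward camera direction, adjusted p = 0.797), were not called.

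Fibroblast and mesenchymal genes lay between the other groups. Fibroblast and matrix genes had 39 of 58 higher and 2 lower in iHep than in hepatocytes (39 and 3 adjusted over the list alone, median 4.31, 4.14 with bounds, adjusted p = 1.78e-10, and adjusted p = 0.330 with an estimated correlation), with Col1a1 up by 9.53 ± 0.61 and Lox by 10.75 ± 0.65 (at least 374.7-fold). Mesenchymal genes likewise had 39 of 65 higher and 2 lower (42 and 3 adjusted over the list alone, adjusted p = 1.63e-11, and adjusted p = 0.163 with an estimated correlation). Proliferation genes had 60 of 67 higher and 2 lower (60 and 2 adjusted over the list alone, median 3.85, 3.70 with bounds, adjusted p = 4.97e-19, and adjusted p = 0.281 with an estimated correlation), and 0 of the 58 that were lower in hepatocytes were called lower in iHep than in MEF. Endothelial genes had 0 of 32 higher and 25 lower (0 and 25 adjusted over the list alone, adjusted p = 6.23e-08, and adjusted p = 0.0822 with an estimated correlation), and Kupffer cell and macrophage genes 1 of 27 and 21 (1 and 21 adjusted over the list alone, adjusted p = 6.96e-07, and adjusted p = 0.163 with an estimated correlation). Since the cell composition of the hepatocyte sample was not measured, these deficits need not be relative to hepatocytes themselves. Intestinal genes were not called as a list, with 17 of 53 higher and 18 lower (17 and 18 adjusted over the list alone, adjusted p = 0.647), a median of -0.49 and a mean of 0.50 with an upward camera direction. Cdx2 rose by 9.65 ± 0.60 (at least 446.5-fold) among them, and Dpp4 fell by 11.51 ± 1.15 (at least 736.1-fold). The fit called 9421 genes, 4232 higher and 5189 lower in iHep, against 10858 with MEF 2 and MEF 3 separate, and 23 of 32 lists. Quantile scaling turned the balance over, to 4920 higher and 4434 lower.

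The overlap of the first 2 comparisons asks how much of the hepatocyte difference was also present in iHep. Of the 5430 genes higher in hepatocytes than in MEF, 1095 (20.2%) were also higher in iHep, against 546 for independent lists of these sizes. Of the 4803 lower genes 1679 (35%) were also lower in iHep, against 636 for independent lists. Together the share was 27.1%, and it was 16.8% without MEF 1. Another 205 genes higher in hepatocytes were lower in iHep, and 189 went the other way. With unchanged groups against the same MEF samples the simulated overlap was 0 in both directions, but such a fit calls almost no gene, so this value does not measure the effect of shared samples. The log2 changes of the 2 comparisons correlated across genes at r = 0.494 against 0.445 simulated, and their covariance was 3.015 against 0.117 simulated, a difference of 2.898. With 1 MEF sample for each comparison, so that they share none, the share was 14.2% (MEF 1 for iHep) and 13% (MEF 2 and MEF 3 for iHep), with fewer genes called. There 424 and 390 genes were higher in both, against 152 and 150 for independent lists, and 636 and 631 lower in both, against 172 and 183. The covariance was 2.902 and 2.918. Part of the excess in the shared fit may come from the shared samples. Of the 5430 genes 4125 (76%) were lower in iHep than in hepatocytes, and of the 4803 genes 3314 (69%) were higher. In 696 genes iHep stood above both other groups and in 652 below both.

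**Figure D3:**
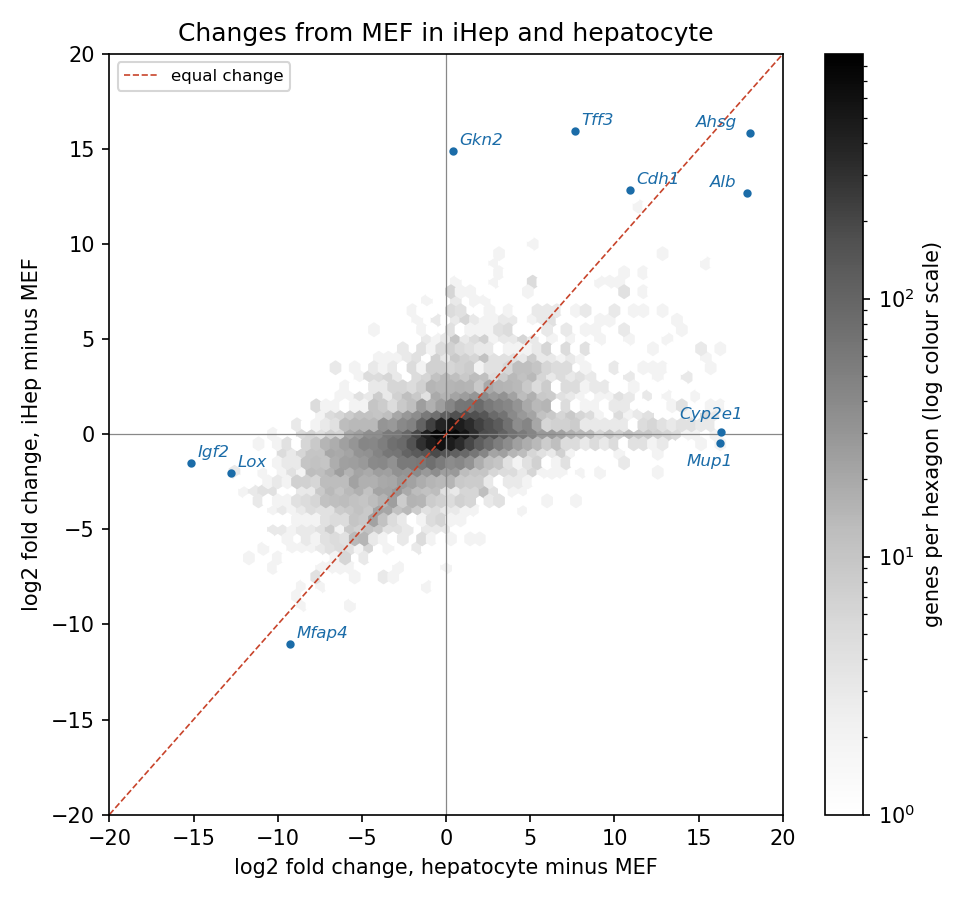
Log2 change of 19135 genes from MEF in hepatocyte (horizontal) and in iHep (vertical), with shading for the number of genes per hexagon and a dashed line for equal change. Ahsg, Alb and Cdh1 lie high on both axes, Gkn2 and Tff3 changed more in iHep than in hepatocyte, and Mup1 and Cyp2e1 lie far out on the hepatocyte axis and were not called in iHep, while Igf2 fell far more in hepatocyte than in iHep.

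Across genes, which are not independent replicates, the arrays correlated with the hepatocyte array at r = 0.686 ± 0.009 for iHep (SD, n = 3) and 0.594 ± 0.003 for MEF (SD, n = 2). The difference of 0.092 had an exact two-sided permutation p of 0.1, the smallest that this design allows. Correlation of the iHep arrays with MEF was 0.868 ± 0.012 (SD, n = 3). On slide 1 alone, MEF 1 correlated with hepatocyte at 0.597 and the iHep arrays at 0.676, 0.694 and 0.688.

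The last comparison concerns the iHep types. Against MEF, 2459 genes were called in type 1 (1117 higher, 1342 lower), 2828 in type 2 (1315 and 1513) and 3394 in type 3 (1481 and 1913), and 799 were higher and 1001 lower in all 3. These fits share the same MEF samples and take their spread from the difference between them, so the counts are no measure of agreement among types. With MEF 2 and MEF 3 separate, the genes that differ between iHep type 1 and MEF numbered 5852, between iHep type 2 and MEF 6290 and between iHep type 3 and MEF 6679. With normexp background correction they numbered 4628, 5223 and 5409. Between types, 375 genes (2.21%) were at least 4-fold apart in types 1 and 2, 690 (4.06%) in types 1 and 3 and 816 (4.75%) in types 2 and 3, compared with 197 (1.12%) between MEF 1 and MEF 2. With normexp the genes at least 4-fold apart between iHep types 1 and 2, types 1 and 3 and types 2 and 3 numbered 146, 295 and 386. All 3 types lay on 1 slide, and differences between them have no replicate check.

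Several liver genes were uneven among the types. Alb was 168.1-fold lower in type 3 than the mean of the others, and the P450 genes Cyp2a5 and Cyp2a12 were at least 181.2-fold and 85.37-fold higher in type 2, with neither well above background in type 3. Cyp2f2, another P450 gene, was 59.39-fold higher in type 2 (2.90 against -1.02 and -4.95). Rpl39l, a ribosomal protein gene, was at 4.41 and 3.53 in types 1 and 2 and not well above background in type 3 (at least 1123-fold lower). Xist, the transcript of the inactive X chromosome, was at 3.42 in type 3 alone (at least 685.9-fold higher) and from 1.26 to 1.87 on the MEF arrays, with a probe on chromosome X at 99666300 to 99666359. Foxa2 was at least 36.84-fold and Aldh1l1 34.84-fold higher in type 1. Reg3b, an antimicrobial lectin of the gut, was 31.35-fold lower there. Lypd8 was at least 95.56-fold lower in type 1, where it was not well above background, and at least 58.50-fold higher in type 2 than the mean of the others. Sftpd, a surfactant protein, was 51.40-fold higher in type 2, Tmem45b was at least 110.6-fold higher in type 3, and Atp12a, a proton pump, was 109.1-fold lower there.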

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

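The test of the sex of the source cells was written before its result was seen, and no other test in this part was. In 4 of the genes named for the iHep types, the reading of 1 type lay above every MEF array and that of another below every MEF array, which is why they are listed here. With 1 array per type, these differences were not tested. The gaps below count a type that was not well above background at the lowest level seen well above background on its array.

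Rpl39l lay at 4.41 and 3.53 in types 1 and 2 and at -8.38, not above background, in type 3, against -2.51 to 0.45 in MEF, a gap of 10.57 between types 1 and 3. Foxa2 lay at -0.94 in type 1 and was not above background in types 2 and 3 (-7.78 and -8.30), against -6.21 to -3.91 in MEF, where MEF 1 was not above background either so that its order with types 2 and 3 is not established, a gap of 5.22 between types 1 and 3. Cyp2f2 was detected in all types, at -1.02, 2.90 and -4.95, against -4.39 to -1.09 in MEF, a gap of 7.86 between types 2 and 3. Xist lay at 3.42 in type 3 and was not above background in types 1 and 2 (-7.97 and -8.30), against 1.26 to 1.87 in MEF, a gap of 9.54 between types 2 and 3.

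Xist and the Y chromosome genes bear on the sex of the source cells. Ddx3y lay at -0.81, 0.79 and -2.50 in types 1, 2 and 3, Eif2s3y at 0.19, 1.55 and -1.97, and on the MEF arrays Xist, Ddx3y and Eif2s3y were all well above background. Type 3 may therefore hold a larger share of female cells than types 1 and 2. Few of the genes that set type 3 apart lie on the sex chromosomes. Of the genes at least 4-fold apart from both others the same way, 4.7% (17 of 363 with a position) lie on X or Y, against 3.4% of all 17140 genes with a position. A percentage of at most 10 had been set beforehand to count against sex as the main cause. It leaves out effects of sex on genes of other chromosomes, however, so this test cannot exclude sex as a cause. With 1 array per type, type and sample cannot be told apart.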

How the results depend on the processing

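The fits with MEF 2 and MEF 3 as separate samples, with and without a replicate block, and with 1 MEF sample for each comparison were chosen after the data had been seen. No called change of a named gene or list reversed under the alternatives in which these were recomputed. They were not recomputed in the fits of MEF and iHep alone and of each iHep type as its own group, with a replicate block or with 1 MEF sample for each comparison. Among all called genes, 1 (iHep against MEF), 3 (hepatocyte against MEF) and 2 (iHep against hepatocyte) were called the other way with normexp, and 0, 16 and 12 with the mean of a gene's probes. The genes that differ between iHep and MEF numbered 4459, and 3317 to 4914 under the other scalings, filters, probe summaries, limma options and the deposited value table. Leaving out 1 replicate gave 1905 (without MEF replicate 1, which leaves 1 MEF sample assumed to vary like the other groups) to 4668 (without iHep replicate 3). They numbered 7307 with MEF 2 and MEF 3 as separate samples, where more samples enter the fit, and 1669 both with slide as a block and within slide 1, where fewer do. At an adjusted p under 0.01 there were 1617, with 6073 between hepatocyte and MEF and 5257 between iHep and hepatocyte. With an estimated correlation, gene lists called between iHep and MEF numbered 0, between hepatocyte and MEF 1 and between iHep and hepatocyte 1, against 23 in each. Glucose and glycogen, hepatocyte transcription factor and endothelial lists had estimated correlations of -0.023, -0.002 and -0.009, under the preset of 0.01. They also lost their calls between iHep and MEF, so a higher correlation between genes is not the cause for these lists. For the lists as a whole the cause was not tested. Of the 23 lists called between iHep and MEF, 15 kept their call with genes above background on all 7 arrays, 20 without iHep replicate 3 and 21 with normexp. Apart from the fit with an estimated correlation, these were the lowest counts of lists kept.

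The share of hepatocyte-MEF differences also called between iHep and MEF ran from 16.8% without MEF replicate 1 to 27.1% without MEF replicate 2, against 27.1%. It was 14.2% and 13% with 1 MEF sample for each comparison, where fewer samples enter each comparison. The genes that differ between iHep type 1 and MEF, iHep type 2 and MEF and iHep type 3 and MEF numbered 4628, 5223 and 5409 with normexp and 5852, 6290 and 6679 with MEF 2 and MEF 3 as separate samples. Without MEF replicate 1 no residual degrees of freedom remain for these fits, so they have no test. With normexp the genes at least 4-fold apart between iHep types 1 and 2, iHep types 1 and 3 and iHep types 2 and 3 numbered 146, 295 and 386. The cause of the normexp changes was not tested. Both ends of the range of the share above are from fits that leave out 1 replicate. The share with MEF 2 and MEF 3 as separate samples is not given here, so the range does not cover the earlier design.

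Of 400 called changes of named genes, 25 lost their call with normexp, 41 without MEF replicate 1 and 0 with MEF 2 and MEF 3 as separate samples. Within slide 1, 37 of 127 did. With a replicate block and MEF 2 and MEF 3 as separate samples the count of genes that differ between iHep and MEF was 5449, against 7307 without the block, and deviations from the group mean correlated at 0.029, -0.015 and -0.001 within numbers, and only the samples numbered 1 correlated best with their own number. On each array 60.2% to 68.7% of probes were well above background, which limits folds of dimmer genes to bounds.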

Other observations

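All tests in this part were chosen after the result was seen. Some genes of the intestinal list were far above MEF in iHep while other abundant intestinal transcripts were not detected. Lgals4, a lectin of gut epithelium chosen here after its values were seen, lay at 6.85, 6.44 and 7.78 in types 1, 2 and 3 against -2.40 to -2.32 on the MEF arrays and 2.48 in hepatocytes. Sis, Muc2 and Slc5a1, also chosen after their values were seen, were not well above background on any iHep array.

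The count of genes that differ between iHep and MEF was compared with the counts from every way to split the 5 samples into 2 and 3. Only 1 of 10 splits, the real one, called 4459 genes, and the highest other count was 0. With 10 splits the share cannot go under 0.1, so this test cannot decide.

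The rise of the intestinal epithelium list in iHep was weighed against a slide batch and against RNA from intestinal tissue, and no biological explanation was tested. Within slide 1 the median log2 difference of the list from MEF 1 averaged 1.67 (SD 0.64, n = 3), so a slide batch is excluded as the whole cause. Of 10 abundant intestinal transcripts 5 were well above background on all 3 iHep arrays (Fabp2, Lct, Anpep, Lgals4 and Guca2a), but these were so on all 3 MEF arrays too. Fabp2 and Lgals4 were higher on every iHep array than on every MEF array, Anpep was lower, and Apoa4 was detected on 2 iHep arrays and 0 MEF arrays. RNA from a tissue rich in Sis, Muc2, Slc5a1 and Anpep as well as Lgals4 would have raised these too, and they were undetected or lower. No intestinal tissue was measured here, so RNA from tissue with little of these transcripts is not excluded.

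The fall of the macrophage list was weighed in the same way. Within slide 1 its median log2 difference from MEF 1 averaged -4.13 (SD 1.20, n = 3), so a slide batch is excluded as the whole cause. All 10 of 10 abundant macrophage transcripts were well above background on every MEF array and lower on every iHep array, among them Lyz2 at 6.02 to 6.67 in MEF and -3.42 to 0.39 in iHep. These transcripts are all members of the macrophage list, so their lower readings restate its fall and do not test its cause. They cannot tell a loss of macrophages from the MEF cultures from lower expression within the cells. No measure of cell composition was used here.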
